A study of Homo sapiens with 6 samples.

How the data were processed

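RNA from BxPC3 cells, an established human pancreatic adenocarcinoma line, was hybridised to 6 Agilent whole human genome arrays with 1 dye. Per the labels, 3 samples carried a control vector and 3 carried a vector expressing a short hairpin RNA (shRNA) against KDM6B, also called JMJD3. The labels describe growth in RPMI medium with fetal bovine serum, column extraction of total RNA and Cy3 labelling with a Quick Amp kit. The design text calls the samples biological triplicates, so the 6 arrays were treated as separate samples, 3 per group. How the shRNA was chosen, whether more than 1 hairpin was used and how long after transfection RNA was taken are not given in the sources used here.

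Spot brightness was deposited as linear intensity from Agilent Feature Extraction 10.5.1.1, per the file headers. The authors' scanner software had already subtracted a spatially fitted background, corrected a multiplicative trend and replaced dim spots by a surrogate value in the processed intensity, per the file headers. A series table held the authors' log2 values for 27575 of the 41000 probes. Set against the scanner values, these deposited log2 values followed the log2 mean intensity without background subtraction (r between 0.999 and 1.00 across probes on each array), and the arrays had near-identical distributions with medians from 9.44 to 9.46. Their scale and direction were therefore settled from the values, they were not centred per gene, and the normalisation that made them is not given in the sources used here. They were used only as an alternative.

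The following choices were fixed before the data were examined: the groups, the fit, the filters, the rule for named genes, the gene lists and most alternatives. Control spots were left out, as were spots marked as non-uniform or population outliers, which numbered 68 to 118 per array. The processed intensity was put on the log2 scale, the 75th percentile of each array's non-control probes was subtracted, and repeat spots of a probe were averaged. A probe was kept when it was well above background on all 3 arrays of at least 1 group, which left 28936 of 41000 probes. Because dim spots were given surrogate values before deposit, folds of probes near background depend on that replacement. For a probe well above background on all arrays of 1 group and on none of the other, the fold is therefore given as "at least": the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background. Such a fold rests on the background handling of the processed intensity and is no lower limit under other handling. Saturated non-control spots numbered 0 on each of the 6 arrays.

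Probe accessions were matched without versions to a RefSeq gene table of assembly GRCh38.p14, used for names only. Of the 41000 probes, 24794 were named by accession, 2533 by symbol and 869 by an older symbol, 1780 kept the name in the file, and 11024 had no gene name. Coordinates are those in the array files, on NCBI build 36 (hg18). No annotation of that build was used here, so exons and untranslated regions are not stated. Each gene was represented by its kept probe with the highest mean signal over the 6 arrays (chosen anew under alternatives that change the values), giving 15312 tested genes; 22 further genes were not tested because an outlier mark left none of their kept probes measured on all 6 arrays. A fit over the kept probes with a gene name, measured on all 6 arrays, covered 5597 genes with at least 2 such probes. Of these genes, 2453 had a probe past the threshold. Among the 2453, 1877 had another probe that did not pass, and 56 had probes past it in opposite directions.

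Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 15312 genes and a threshold of 0.05. Changes are shKDM6B minus control on the log2 scale with limma standard errors, and levels are log2 values relative to each array's 75th percentile. Values of single probes of a gene come from a fit over all 28936 kept probes. The 36 gene lists were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01, adjusted over the 35 lists with at least 5 tested genes. Camera with an estimated correlation and fry were run as alternatives. Fry tests whether a list's genes move one way on balance and does not compare them with other genes. Tables were assembled with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.

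The lists covered H3K27 demethylases, Polycomb repressive complex 2 (PRC2), COMPASS-like complexes, C/EBP factors, genes linked to C/EBPα, cyclin-dependent kinase inhibitors, G1/S genes, G2/M genes, NF-kB and inflammatory genes, interferon-stimulated genes, mesenchymal genes, epithelial junctions, duct, acinar and islet markers, classical and basal-like pancreatic cancer genes, mucins and invasion proteases. They also covered targets of TGF-beta, MAPK and WNT signalling, NOTCH genes, immediate early and heat shock genes, unfolded protein and amino acid stress genes, hypoxia and glycolysis, cholesterol and fatty acid synthesis, p53 targets, HOX genes, apoptosis regulators, fibroblast, leukocyte and endothelial markers, ribosomal proteins, reference genes and replication histones. Named genes were KDM6B and CEBPA; the 10 largest rises and 10 largest falls among changed genes well above background on all 6 arrays with no overlap between the groups; the 3 largest bounds each way; and up to 4 changed members of each list by smallest adjusted p, or the 2 brightest members where none changed. Other genes were named after their values were seen, and are said to be. Some genes that this rule names are not reported here.

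The array files also gave slide and scan date. The first scan held control 1, control 2 and shKDM6B 2, and the second held control 3, shKDM6B 1 and shKDM6B 3. Of the 3 slides, slide 1 held control 1 and shKDM6B 2, slide 2 held control 2, and slide 3 held control 3, shKDM6B 1 and shKDM6B 3. Scan and slide were each fitted as a block, and changes were computed within each scan and within slides 1 and 3. Slide 3 holds the same arrays as the second scan, so its values repeat that scan's. Slide 1 sets 1 array against 1. Control 2 is alone on its slide, so with slide as a block it adds nothing to the comparison. Other alternatives were normexp background correction with an offset of 50, quantile normalisation, the median in place of the 75th percentile, other filters on dim probes, outlier spots kept, the mean of a gene's probes, each probe on its own, the authors' log2 values, intensity trend with robust settings, array quality weights, the replicate number as a block, and each array left out in turn. Removing each array's trend on probe GC content, and leaving out both arrays numbered 3, were added after seeing the data.

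The fits were tested on simulated values for the 15312 genes with 200 genes changed by a known fold. Of genes changed 1.5-fold, 8 of 67 were called (11.9%), of those changed 2-fold 40 of 67 (59.7%), and of those changed 4-fold 50 of 66 (75.8%), while 3 of 15082 unchanged genes were called. A simulated list of 30 shifted genes was called and an unshifted list of 30 was not. The simulated genes varied independently and without a scan effect, and far fewer changed than the 4190 called in the data. These rates and list calls therefore need not hold for the data. With 3 arrays per group, the number of arrays limits the precision.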

Results

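Gene expression was measured on 6 whole-genome arrays of BxPC3 cells, a line derived from a human pancreatic adenocarcinoma: 3 of cells with a control vector and 3 of cells with a vector expressing an shRNA against KDM6B. KDM6B (JMJD3) is a demethylase that removes methyl groups from lysine 27 of histone H3, a mark written by PRC2. The comparison asks which genes depend on KDM6B in these cells, and the series title names C/EBPα, the product of CEBPA, as lowered by its loss. Of 41000 probes, 71.5% to 78.7% were well above background on the control arrays and 68.3% to 75.8% on the shKDM6B arrays. Repeat spots of a probe within an array had a median SD of 0.054 to 0.074 on the log2 scale.

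Arrays of one group resembled each other more than arrays of different groups. Across the 15312 genes tested, which are not independent replicates, r was 0.985 to 0.997 within groups and 0.966 to 0.977 between them. The median gene had an SD of 0.15 among control arrays and 0.20 among shKDM6B arrays (log2, n = 3 each). The first principal component held 62.6% of the variance and separated the groups. The second held 25.6% and separated the scan dates. In both groups it also ordered the arrays by replicate number, with array 3 lowest and array 2 highest. It therefore cannot be assigned to scan date alone. The first scan held control 1, control 2 and shKDM6B 2, and the second held the other three arrays. Blocked and within-scan values are therefore given for KDM6B, KDM6A, CEBPA, the genes with the largest rise and fall, the count of changed genes and the lists that shifted.

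The KDM6B transcript was lower in all 3 shKDM6B arrays than in any control array. Its single kept probe, A_24_P942630, at chromosome 17, bases 7698052 to 7698111 on the plus strand (hg18), measured −5.37 ± 0.04 in control and −6.90 ± 0.21 in shKDM6B (log2 relative to each array's 75th percentile, SD, n = 3). KDM6B fell by 1.53 ± 0.14 (SE; limma adjusted p = 0.000687). The probe was dim: it was well above background on the 3 control arrays and on 0 of the 3 shKDM6B arrays. By the rule for such probes the fold is at least 2.88. That value is close to the plain fold of 2.89 and is no lower limit under other background handling. Within the first scan the change was −1.27 and within the second −1.69, and with scan as a block it was −1.48 (adjusted p = 0.000638). After normexp background correction it was −0.37 ± 0.15 and missed the threshold (adjusted p = 0.109), the highest of 20 alternatives that gave values from 4.4e-05.

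KDM6A (UTX), the other H3K27 demethylase on the fixed list, rose by 0.64 ± 0.14 (1.56-fold, adjusted p = 0.0154). Its probe lies on chromosome X, bases 44856292 to 44856351. KDM6A measured 1.08 ± 0.05 in control and 1.73 ± 0.21 in shKDM6B (SD, n = 3), with changes of 0.43 and 0.79 within the scans and an adjusted p of 0.0153 with scan as a block. The call was lost without control 1 (adjusted p = 0.0648) or control 2 (0.0574), and over 22 alternatives the adjusted p ran from 0.000812 to 0.0677.

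CEBPA, which encodes a transcription factor of myeloid, fat and liver differentiation, was measured by 3 probes on chromosome 19 (minus strand). Probe A_23_P375494, at bases 38482988 to 38483047, measured 1.72 ± 0.05 in control and 0.51 ± 0.19 in shKDM6B, and fell by 1.21 ± 0.14 (2.32-fold, adjusted p = 0.00275). Probe A_24_P224727, at bases 38483193 to 38483252, fell by 1.20 ± 0.16 (2.29-fold, adjusted p = 0.00460), from 1.67 ± 0.09 to 0.47 ± 0.26 (SD, n = 3). Within the 2 scans these probes gave −1.28 and −1.16, and −1.27 and −1.24. The brightest CEBPA probe, A_24_P216165, which represents the gene and lies furthest 5′ at bases 38484724 to 38484783, measured 4.40 ± 0.63 in control and 3.23 ± 1.23 in shKDM6B, a change of −1.17 ± 0.63 (SE) that did not pass (adjusted p = 0.216).

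The brightest CEBPA probe varied with scan date, and 81.7% of its bases are G or C, against 43.3% and 48.3% for the other two. Within the scans its change was −1.98 and −1.31. With scan as a block it was −1.64 ± 0.37 and passed (adjusted p = 0.0180), with slide as a block −1.58 (adjusted p = 0.00485), and without shKDM6B 3 it was −1.81 (adjusted p = 0.0491). Without control 3 it was −0.80, and without shKDM6B 2 −0.58. Over 24 alternatives, the other two probes included, the adjusted p for CEBPA ran from 0.00275 to 0.438.

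**Figure D1:**
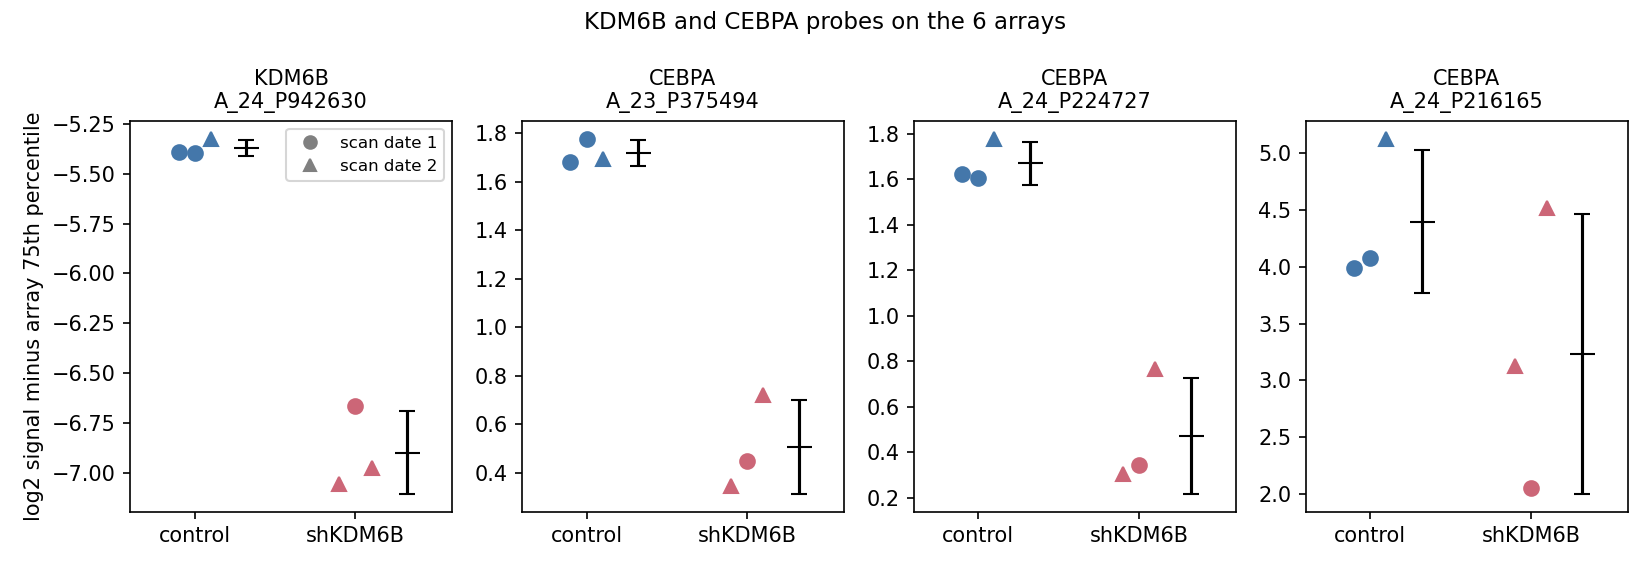
Signal of the KDM6B probe and the 3 CEBPA probes (log2 relative to each array's 75th percentile) on each array, circles for the first scan and triangles for the second, with bars for the mean ± SD (n = 3). The KDM6B probe and the CEBPA probes A_23_P375494 and A_24_P224727 separate the groups, while the ranges of the brightest CEBPA probe, A_24_P216165, overlap.

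Of the 7 C/EBP family members tested, CEBPD rose by 0.58 ± 0.17 (adjusted p = 0.0409) and the other six did not pass. Adjusted over the list alone, none of the C/EBP members passed, and the list was not shifted (camera adjusted p = 0.970; its median of 0.03 and mean of −0.09 differ in sign). CEBPB, another C/EBP factor, measured 0.18 ± 0.12 and missed the threshold; it was named after its value was seen. Without control 1 the CEBPD call was lost (adjusted p = 0.142), as it was without control 2 (0.137), shKDM6B 1 (0.103) or shKDM6B 3 (0.0797), and with slide as a block (0.0528); its 22 alternatives ran from 0.00207 to 0.142. Of 13 genes linked to C/EBPα, 6 rose and 7 did not pass, and adjusted over the list alone 6 rose. S100A8 and S100A9, calcium-binding proteins of neutrophils and inflamed epithelium, rose by 3.89 ± 0.15 (14.9-fold) and 1.31 ± 0.17. TRIB1, a pseudokinase that promotes degradation of C/EBPα, rose by 0.82 ± 0.12, although a second TRIB1 probe (0.69) did not pass. LCN2, a siderophore-binding protein, rose by 0.93 ± 0.19, a call lost without control 1 (adjusted p = 0.0633). The list was not shifted against other genes (camera adjusted p = 0.103).

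Among genes well above background on all 6 arrays, the 10 with the largest rises included 3 of the SPRR family. SPRR2D, a small proline-rich envelope protein, rose by 6.60 ± 0.14 (96.8-fold), SPRR2C, a pseudogene of that family, by 6.54 ± 0.15 (93.0-fold) and SPRR1A by 4.15 ± 0.12 (17.7-fold). IL36G, an epithelial cytokine of the IL-1 family, rose 50.8-fold, FDCSP, a small secreted protein, 42.9-fold, CCL3, a chemokine, 33.4-fold and IL19, a cytokine of the IL-10 family, 17.2-fold. PDZK1IP1, a small membrane protein, rose 22.4-fold, SERPINB7, a serine protease inhibitor, by 4.40 ± 0.23 on the log2 scale, and WFDC5, a WAP-domain protease inhibitor, 18.3-fold. The SEs of these changes were 0.11 to 0.28 (log2, n = 3 per group), and the highest adjusted p, for IL19, was 0.000281. Near-identical family members can share probe signal, so SPRR2D, SPRR2C and CCL3 are uncertain as single genes. The SPRR1A probes disagree in size: the brightest, A_23_P74012, gives the value above, and the other, A_23_P348208, rose by 1.49, so the place of SPRR1A among the largest rises rests on 1 of 2 probes. The same holds for WFDC5, whose second probe rose by 2.84. After normexp and in the authors' log2 values the other SPRR1A probe was the brighter and stood for SPRR1A (1.45 and 1.36). CCL3 rose by 3.25 after normexp.

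Among the same genes the largest fall was in H19, an imprinted noncoding RNA, which fell by 4.48 ± 0.23 (22.3-fold). ALDH1A1, a retinaldehyde dehydrogenase, fell 17.5-fold, KRT4, a keratin of mucosal epithelium, 12.6-fold and MMP12, an elastase, changed by −3.40 ± 0.22. AOC1, which degrades histamine, fell 9.20-fold, ALPP, placental alkaline phosphatase with close paralogs that can share its signal, 9.04-fold and LYPD2, a surface protein, 8.82-fold. CSPG4, a membrane proteoglycan, fell 7.19-fold, DUSP9, a MAP kinase phosphatase, 7.11-fold and CYP4B1, a cytochrome P450, 6.14-fold. The SEs were 0.11 to 0.31 (log2), and the highest adjusted p, for ALDH1A1, was 0.000366. Over 22 alternatives the log2 change of ALDH1A1 ran from −4.51 to −2.76, so its fold depends on processing. Within the scans SPRR2D changed by 6.73 and 6.35 and H19 by −3.95 and −4.81, and with scan as a block these changes were 6.54 and −4.38.

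Some genes were measured above background in 1 group only. NLRP7, a cytoplasmic pattern-recognition protein, rose at least 122-fold, PPBP, a neutrophil-attracting chemokine, at least 58.8-fold and ESM1, a secreted proteoglycan, at least 47.5-fold. KCNE3, a potassium channel subunit, fell at least 19.6-fold, BPIFB1, a secreted mucosal protein, at least 8.79-fold and VCAM1, a leukocyte adhesion molecule, at least 8.22-fold. The adjusted p of these 6 genes was at most 0.00278, and 18 genes rose and 55 fell with such a bound. After normexp these changes were smaller and still past the threshold: 2.88 for NLRP7, 2.34 for PPBP, 1.94 for ESM1, −1.38 for KCNE3, −0.84 for BPIFB1 and −1.19 for VCAM1. In the authors' log2 values they were 3.27, 2.69, 2.26, −1.59, −0.94 and −1.38. The values of both alternatives are on the log2 scale, so the folds above are no lower limits under other background handling.

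**Figure D2:**
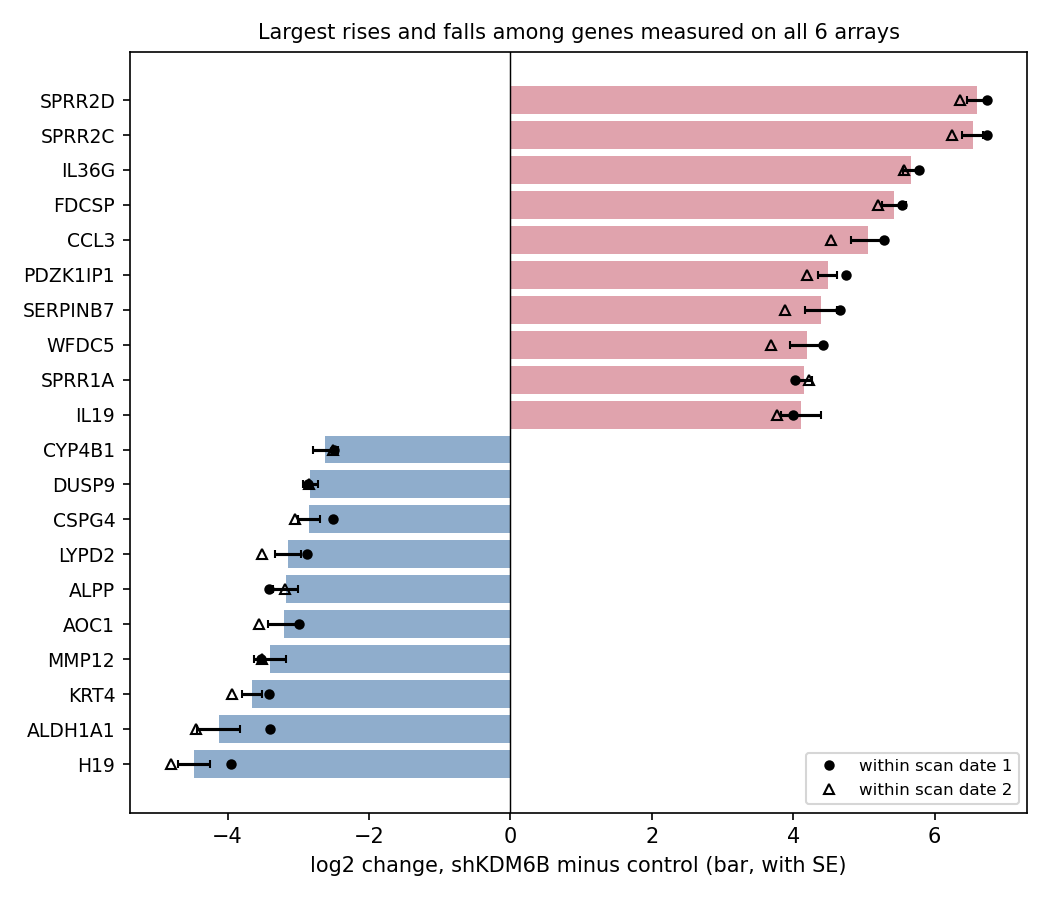
Log2 change (shKDM6B minus control, bars with SE from limma, n = 3 arrays per group) of the 10 genes with the largest rise and the 10 with the largest fall, with points for the change within each scan. The genes were chosen among those whose groups do not overlap, and run from SPRR2D at 6.60 to H19 at −4.48.

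In all, 4190 of 15312 genes (27.4%) changed at a limma adjusted p under 0.05: 2376 were higher and 1814 lower in shKDM6B. The excess of rises depends on scaling: 56.7% of changed genes were higher here, against 48.9% with the median in place of the 75th percentile (1797 higher, 1881 lower), 50.3% after quantile normalisation and 49.9% in the authors' log2 values. Of the 4190 changed genes, 689 rose and 465 fell at least 2-fold. The groups did not overlap for 7006 genes (45.8%), against 10% by chance for 3 against 3. With scan as a block 5361 genes passed, 4170 of them among the 4190. With slide as a block 4555 passed. The count depended on single arrays: it was 1971 without control 1 (1134 higher, 837 lower), 2209 without control 2 (1280 and 929) and 2283 without shKDM6B 1 (1321 and 962). At least 2-fold changes numbered 666 after normexp and 706 in the authors' log2 values, against 1154 here.

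NF-kB and inflammatory genes rose as a group: 22 of 28 members rose and the other six did not pass, with a median change of 1.33. PTGS2, the inducible prostaglandin synthase, rose by 3.95 ± 0.16 (15.4-fold), CSF2, which encodes GM-CSF, by 3.57 ± 0.11 (11.9-fold), IL23A, a subunit of IL-23, by 3.36 ± 0.12 (10.3-fold) and CXCL8, which encodes IL-8, by 3.03 ± 0.14 (8.14-fold). Adjusted over the list alone 23 rose. The list was shifted up against other genes (camera adjusted p = 2.0e-12), but not with an estimated correlation (adjusted p = 0.227 with an estimated correlation). With scan as a block the median was 1.33 (adjusted p = 5.7e-12). The medians within the scans were 1.32 and 1.24, and within slides 1 and 3 they were 1.26 and 1.24. Slide 3 holds the arrays of the second scan, so its medians repeat that scan's, here and for the lists below.

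G2/M and mitosis genes were lower as a group: 11 of 29 fell and 18 did not pass, with a median change of −0.40. MKI67, a proliferation marker, fell by 1.07 ± 0.13 (2.11-fold). CDC25C, a phosphatase that activates CDK1, changed by −0.81 ± 0.13, BUB1B, a spindle checkpoint kinase, by −0.79 ± 0.11 and AURKA, a mitotic kinase, by −0.64 ± 0.11, each past the threshold. Adjusted over the list alone 14 fell. The shift against other genes passed (camera adjusted p = 7.2e-05), but not with an estimated correlation (adjusted p = 0.260 with an estimated correlation). Blocked by scan, the median was −0.32 (adjusted p = 0.000200). The medians were −0.36 within each scan and −0.33 and −0.36 within slides 1 and 3.

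Among 25 G1/S and replication genes, 9 fell, 1 rose and 15 did not pass (12 and 2 adjusted over the list alone). MCM2, a subunit of the replicative helicase, and ORC1, a subunit of the origin recognition complex, fell by 0.82 ± 0.12 and 0.80 ± 0.13. The median change of −0.19 did not pass (camera adjusted p = 0.0737), and passed only under some settings, such as without shKDM6B 1 (adjusted p = 0.0323). Of 6 cyclin-dependent kinase inhibitors, 2 rose, 2 fell and 2 did not pass, with the same counts adjusted over the list alone. CDKN1C, an imprinted inhibitor, fell by 1.65 ± 0.11 (3.15-fold). CDKN2D, CDKN2C and CDKN1A passed with adjusted p of 0.0253, 0.0291 and 0.0495, at changes of 0.62, −0.58 and 0.42. Leaving out 1 array ended the CDKN2C call for each of the 6 arrays (adjusted p 0.0519 to 0.0755), the CDKN1A call for all but shKDM6B 1 (0.0756 to 0.172) and the CDKN2D call for all but control 3 and shKDM6B 2 (0.0570 to 0.107). With slide as a block CDKN1A missed the threshold too (0.0920), and its 22 alternatives ran from 0.0190 to 0.172. The inhibitor list was not shifted (camera adjusted p = 0.740; its median of 0.16 and mean of −0.15 differ in sign).

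Cholesterol and fatty acid synthesis genes were higher as a group: 14 of 28 rose, 1 fell and 13 did not pass, with a median change of 0.40. HMGCS1 and SQLE, enzymes of the mevalonate and sterol pathway, rose by 1.85 ± 0.18 (3.61-fold) and 1.69 ± 0.17 (3.22-fold). INSIG1, a sterol-regulated inhibitor of SREBP processing, rose by 0.89 ± 0.11 (1.86-fold). FADS2, a fatty acid desaturase named after its value was seen, was the member that fell. Adjusted over the list alone 15 rose and 1 fell. The list was shifted up (camera adjusted p = 0.00170), but not with an estimated correlation (adjusted p = 0.565 with an estimated correlation). Blocked by scan, the median was 0.41 (adjusted p = 0.000920). The medians within the scans were 0.38 and 0.46, and within slides 1 and 3 they were 0.42 and 0.46.

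**Figure D3:**
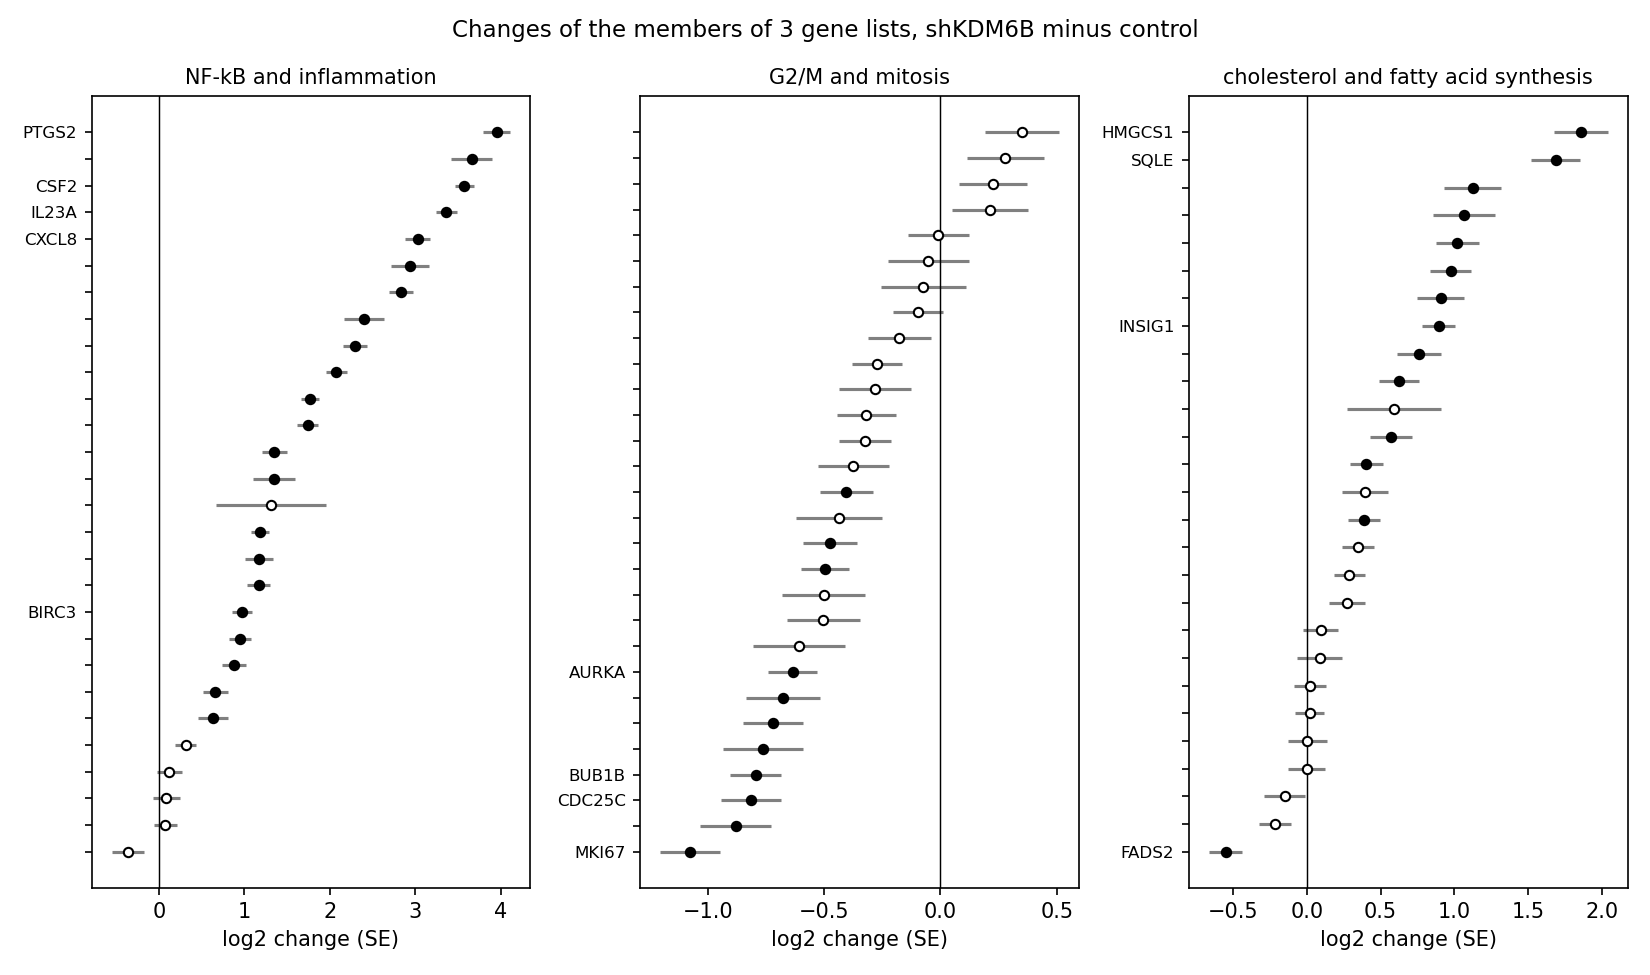
Log2 change (shKDM6B minus control, with SE, n = 3 arrays per group) of members of the NF-kB and inflammatory, G2/M, and cholesterol and fatty acid synthesis lists (1 member of the last is not drawn), filled where the gene passed the threshold and open where it did not, with names for genes given in the text. Of the members, 22 of 28 rose, 11 of 29 fell and 14 of 28 rose, respectively.

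These 3 of 35 tested lists passed with the preset correlation, while with an estimated one the lowest adjusted p was 0.227, for the NF-kB list. By fry, which asks whether a list moves one way on balance without comparing it with other genes, 16 lists passed, 14 upwards and 2 downwards. The NF-kB, G2/M and cholesterol calls held in each fit that left out 1 array. Without shKDM6B 1, 6 lists passed, the further ones being G1/S (adjusted p = 0.0323), basal-like (0.0234) and hypoxia genes (0.0234). Blocked by scan, the same 3 lists passed, and with slide as a block hypoxia genes did too (adjusted p = 0.0471).

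Genes of the basal-like state and of keratinocyte differentiation changed both ways: of 34, 14 rose, 6 fell and 14 did not pass (17 and 7 adjusted over the list alone). SPRR1B and SPRR3, further envelope proteins, rose by 3.45 ± 0.12 and 2.82 ± 0.12 (7.06-fold). The list missed the threshold (camera adjusted p = 0.0737). By camera it passed without shKDM6B 1 (0.0234), with the mean of a gene's probes (0.0139) and with each probe on its own (0.00775). It also passed by fry (0.00294), and missed the threshold under the other alternatives. Of 24 genes of the classical state of pancreatic cancer, 6 fell, 1 rose and 17 did not pass, with the same counts adjusted over the list alone. ELF3, an epithelial transcription factor, VSIG2, a membrane protein, and AGR2, a protein disulfide isomerase, changed by −1.24 ± 0.17, −1.26 ± 0.17 and −1.12 ± 0.19. TFF1, a secreted trefoil peptide, rose by 1.17 ± 0.12 (0.74 for a second TFF1 probe). The classical list was not shifted (camera adjusted p = 0.164).

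Of 13 duct markers, 2 rose, 5 fell and 6 did not pass, and adjusted over the list alone 3 rose and 5 fell. CFTR, the epithelial chloride channel, was well above background on 1 of 3 control arrays and on all 3 shKDM6B arrays, and rose by 6.21 ± 0.10 (1.90 after normexp and 2.19 in the authors' log2 values). SOX9, a transcription factor of duct cells, rose by 2.54 ± 0.17 (5.82-fold), whereas TSPAN8, a tetraspanin, fell by 2.34 ± 0.10 (5.08-fold) and KRT7, a duct keratin, fell by 0.80 ± 0.15. The list was not shifted (camera adjusted p = 0.740), and its median of −0.05 has the opposite sign to its mean of 0.34. Of 11 acinar markers PRSS2 and PRSS3, both trypsinogens with near-identical copies, rose by 0.70 ± 0.15 and 0.60 ± 0.14 and 9 did not pass (2 rose adjusted over the list alone; camera adjusted p = 0.282). Their calls were lost without control 1, control 2 or shKDM6B 1 (adjusted p 0.0657 to 0.0828 for PRSS2 and 0.0781 to 0.0972 for PRSS3), and that of PRSS3 also without shKDM6B 3 (0.0543). The 13 islet markers did not pass limma's threshold over all genes or over the list alone, and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.740). The brightest were NEUROG3, an endocrine progenitor factor, at −1.28 ± 0.42, and MAFA, a beta-cell factor, at 0.29 ± 0.36. NEUROG3 passed with scan as a block (−1.44, adjusted p = 0.0367) and with slide as a block (adjusted p = 0.0144), in a range of 0.00230 to 0.210 over 22 alternatives. PCSK1, a prohormone convertase named after its value was seen, passed with scan as a block (0.41, adjusted p = 0.0438).

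Of 9 mucins, MUC13 rose by 3.10 ± 0.36 and 8 did not pass (1 rose adjusted over the list alone; camera adjusted p = 0.737). MUC13, a membrane mucin, was well above background on 1 of 3 control arrays, and its rise was 0.88 after normexp and 1.05 in the authors' log2 values. Of 24 epithelial junction genes, 8 rose, 3 fell and 13 did not pass (9 and 4 adjusted over the list alone; camera adjusted p = 0.226). CLDN3 and OCLN, tight junction proteins, rose by 3.75 ± 0.20 (13.5-fold) and 1.46 ± 0.22, OVOL1, an epithelial repressor, by 1.26 ± 0.16 and MAL2, an apical transport protein, by 0.72 ± 0.10. A second CLDN3 probe rose by 1.12, and the mean of both by 2.44. Of 16 mesenchymal genes, 5 rose, 2 fell and 9 did not pass, with the same counts adjusted over the list alone and a camera adjusted p of 0.226. VIM, an intermediate filament, FN1, a matrix glycoprotein, and SNAI1, a repressor of E-cadherin, rose by 2.69 ± 0.13 (6.44-fold), 2.65 ± 0.24 (6.28-fold) and 2.52 ± 0.12 (5.73-fold). S100A4, a calcium-binding protein of motile cells, fell by 1.13 ± 0.12. Of 27 invasion proteases and their inhibitors, 9 rose, 8 fell and 10 did not pass (11 and 8 adjusted over the list alone; camera adjusted p = 0.740). MMP7 (matrilysin) and PLAT (tissue plasminogen activator) rose by 2.05 ± 0.12 and 1.78 ± 0.11. MMP13, a collagenase, fell by 2.26 ± 0.12 and TIMP3, a metalloprotease inhibitor, fell by 1.62 ± 0.11.

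Signalling targets changed both ways, and these lists were not shifted by camera. Of 23 TGF-beta targets, 6 rose, 5 fell and 12 did not pass (6 and 7 adjusted over the list alone; camera adjusted p = 0.980). INHBA, a subunit of activin, and ID3, an inhibitor of DNA binding, rose by 2.57 ± 0.11 (5.94-fold) and 1.72 ± 0.15, while CCN2 and THBS1, matricellular proteins, changed by −2.14 ± 0.19 and −0.94 ± 0.13. Of 22 output genes of RAS and MAPK signalling, 7 rose, 1 fell and 14 did not pass (8 and 2 adjusted over the list alone; camera adjusted p = 0.342). EREG and AREG, ligands of the EGF receptor, rose by 2.69 ± 0.12 (6.46-fold) and 1.34 ± 0.14, and CCND1, which encodes cyclin D1, fell by 0.95 ± 0.12. Of 14 WNT targets, 4 rose, 3 fell and 7 did not pass, also adjusted over the list alone (camera adjusted p = 0.740). LEF1, a WNT transcription factor, rose by 1.98 ± 0.18 (3.96-fold), and TCF7, of the same family, and ASCL2 changed by −0.84 ± 0.11 and −0.95 ± 0.10. After normexp the TCF7 change was −0.55. Of 12 NOTCH genes, 3 rose, 4 fell and 5 did not pass, also adjusted over the list alone (camera adjusted p = 0.565). The receptor gene NOTCH2 and the ligand gene JAG1 rose by 1.16 ± 0.13 and 1.04 ± 0.13, and the ligand gene DLL1 fell by 0.77 ± 0.10.

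Of 33 interferon-stimulated genes, 5 rose, 8 fell and 20 did not pass, also adjusted over the list alone (camera adjusted p = 0.740). IFI27 and USP18, an ISG15 protease, rose by 1.84 ± 0.15 and 1.14 ± 0.13 (0.50 for a second USP18 probe), while IFIT3 and the GTPase gene GBP1 changed by −1.45 ± 0.16 and −1.15 ± 0.15. Of 28 hypoxia and glycolysis genes, 10 rose, 1 fell and 17 did not pass, also adjusted over the list alone (camera adjusted p = 0.0737). By camera this list passed without shKDM6B 1 (0.0234), after normexp (0.0310) and with slide as a block (0.0471). It also passed with the mean of a gene's probes (0.0452), with each probe on its own (0.0181) and by fry (0.00126). Under the other alternatives it missed the threshold. ANGPTL4, a lipase inhibitor, and ANKRD37 rose by 2.55 ± 0.16 (5.86-fold) and 1.38 ± 0.10, and EGLN1, an oxygen-sensing hydroxylase, by 1.30 ± 0.11, while a further EGLN1 probe (0.32) did not pass. Of 25 unfolded protein and amino acid stress genes, 5 rose, 9 fell and 11 did not pass (5 and 10 adjusted over the list alone; camera adjusted p = 0.164). SESN2, a stress-induced inhibitor of mTORC1, fell by 1.37 ± 0.15, PSAT1, of serine synthesis, fell by 0.93 ± 0.11 and VLDLR, a lipoprotein receptor, rose by 1.22 ± 0.11. Of 20 immediate early and heat shock genes, 6 rose and 14 did not pass (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.418). HSPH1, a chaperone, rose by 1.09 ± 0.16.

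Of 26 p53 targets, 7 rose, 5 fell and 14 did not pass (8 and 5 adjusted over the list alone; camera adjusted p = 0.980). GADD45A, a DNA damage-induced gene, rose by 1.26 ± 0.11 and TP53INP1, a stress-induced p53 partner, fell by 0.92 ± 0.11. The p53 list's median of −0.05 has the opposite sign to its mean of 0.10. Of 24 apoptosis regulators, 8 rose, 4 fell and 12 did not pass (8 and 5 adjusted over the list alone; camera adjusted p = 0.565). CFLAR, an inhibitor of caspase 8 activation, and BIRC3, an inhibitor of apoptosis, rose by 1.54 ± 0.12 (0.75 for a second CFLAR probe) and 0.97 ± 0.12, as did BIK, a death-promoting BCL2 relative, by 1.01 ± 0.13.

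Genes for chromatin complexes changed in both directions. Of 11 PRC2 genes, EZH2, a methyltransferase, rose by 0.62 ± 0.18 (adjusted p = 0.0453), EZH1, its homolog, fell by 0.64 ± 0.13 (0.0149), MTF2, a cofactor, fell by 0.36 ± 0.10 (0.0417) and 8 did not pass (camera adjusted p = 0.565; 1 rose and 2 fell adjusted over the list alone). Each call was lost without 1 of several arrays: EZH1 without control 1 or shKDM6B 1 (adjusted p = 0.0562 and 0.0591), EZH2 without any but shKDM6B 2 (0.0824 to 0.136) and MTF2 without any but shKDM6B 2 (0.0615 to 0.192). With slide as a block MTF2 also missed the threshold (0.129), in a range of 0.00518 to 0.192 over its alternatives. Of 11 COMPASS-like genes, 2 rose, 2 fell and 7 did not pass, also adjusted over the list alone (camera adjusted p = 0.740). KMT2A, an H3K4 methyltransferase, rose by 0.91 ± 0.15, but its 4 probes averaged gave 0.49 and missed the threshold (adjusted p = 0.104, the highest of 22 alternatives, from 0.000258). Of 22 HOX genes, 3 rose, 5 fell and 14 did not pass (4 and 5 adjusted over the list alone; camera adjusted p = 0.610). HOXC13 and HOXA7, transcription factors of body patterning, changed by −0.69 ± 0.13 and −1.04 ± 0.19, and after normexp by −0.38 and −0.66. The HOXC13 change missed the threshold after normexp (adjusted p = 0.112) and the HOXA7 change without both arrays numbered 3 (0.0662), in ranges of 0.000692 to 0.112 and 0.000956 to 0.0662 over their alternatives.

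**Figure D4:**
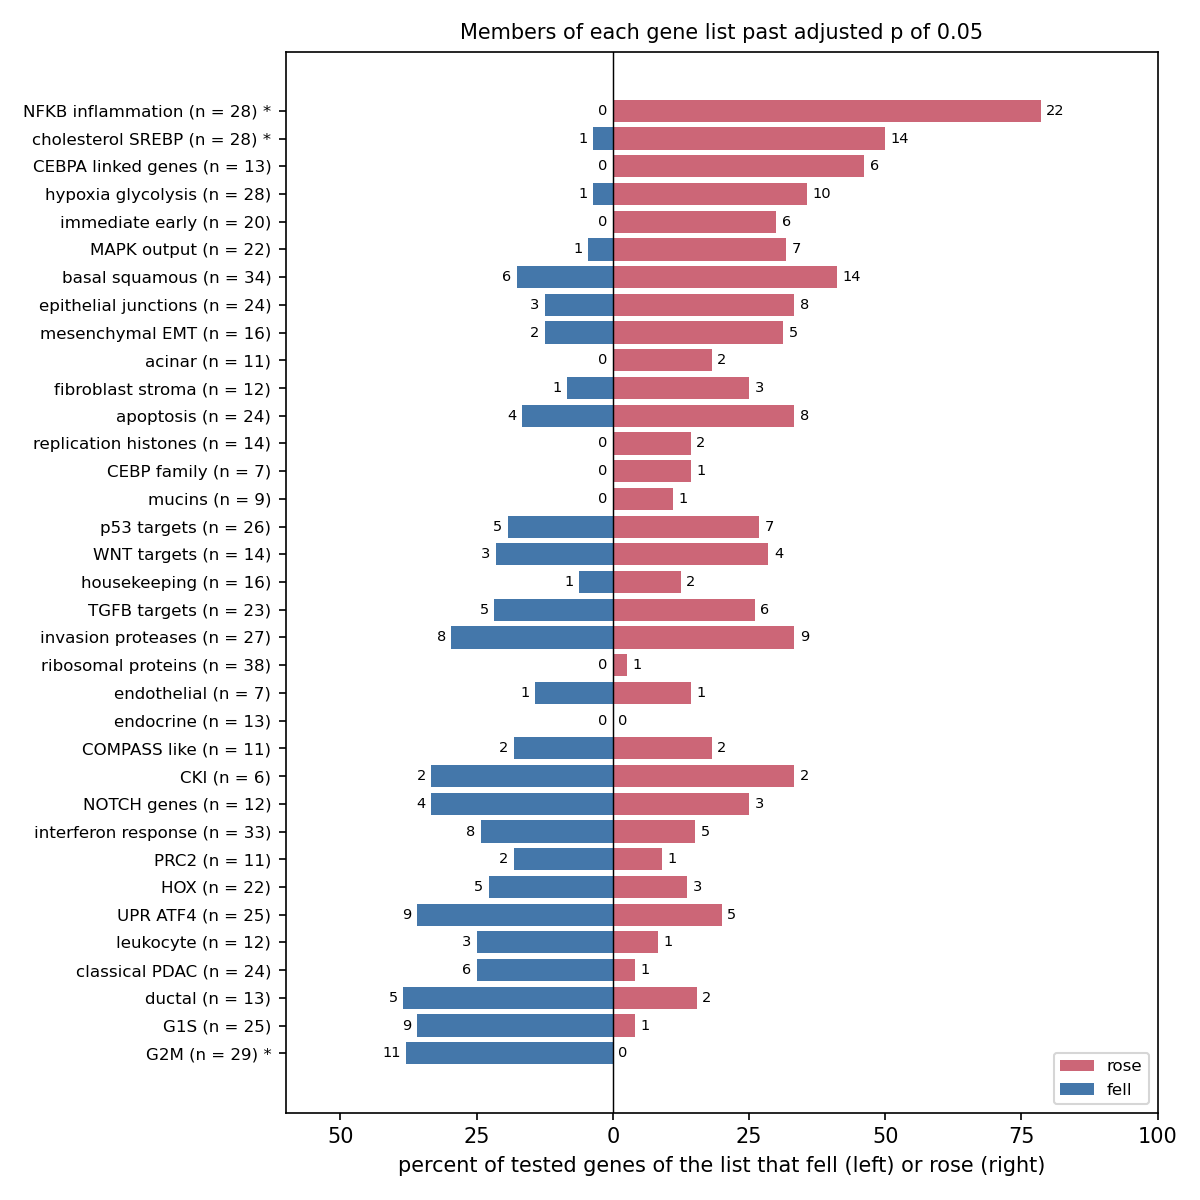
Share of the tested members of each gene list that rose (right) or fell (left) past an adjusted p of 0.05 in shKDM6B, in percent, with the counts printed and an asterisk for lists shifted by camera with the preset correlation. The NF-kB and inflammatory list, with 22 of 28 members higher, has the largest share of rises.

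Markers of other cell types changed in both directions. Of 12 fibroblast markers, 3 rose, 1 fell and 8 did not pass, also adjusted over the list alone (camera adjusted p = 0.696): COL5A1, a collagen, rose by 0.86 ± 0.13 and FBLN1, a matrix protein, fell by 0.78 ± 0.16. The COL5A1 call was lost after normexp (adjusted p = 0.112, the highest of 22 alternatives, from 0.00151). Of 12 leukocyte markers tested, 1 rose, 3 fell and 8 did not pass, also adjusted over the list alone (camera adjusted p = 0.740; its median of 0.12 and mean of −0.07 differ in sign). LAPTM5, a lysosomal protein of blood cells, fell by 0.62 ± 0.15, a call lost without control 1 (adjusted p = 0.100), control 2 (0.0960), shKDM6B 1 (0.0856) or shKDM6B 3 (0.0634). A second LAPTM5 probe (−0.38) did not pass, and it stood for the gene after normexp, where the call was lost too (0.0546), in a range of 0.000737 to 0.100 over 22 alternatives. Of 7 endothelial markers, TEK, an angiopoietin receptor, rose by 2.93 ± 0.14 (7.61-fold), PECAM1, an adhesion molecule, fell by 0.39 ± 0.11 and 5 did not pass, also adjusted over the list alone (camera adjusted p = 0.740). The PECAM1 call was lost without any single array but shKDM6B 3 (adjusted p 0.0501 to 0.177) and with slide as a block (0.107). The TEK rise was 1.71 after normexp and 1.89 in the authors' log2 values.

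Ribosomal, reference and histone genes served as a check of scaling. Of 38 ribosomal protein genes, 1 rose and 37 did not pass, and adjusted over the list alone that rise did not pass. The ribosomal median was 0.27 here and 0.02 after quantile normalisation, and within the scans it was −0.02 and 0.28. The list was not shifted (camera adjusted p = 0.200), except without shKDM6B 2 (0.000907) and with array quality weights (0.00152), in a range of 0.000907 to 0.934 over 24 alternatives. Of 16 reference genes, 2 rose, 1 fell and 13 did not pass (none adjusted over the list alone; camera adjusted p = 0.740). YWHAZ, a signalling adaptor, rose by 0.46 ± 0.11 and SDHA, a subunit of succinate dehydrogenase, fell by 0.40 ± 0.12 (a second SDHA probe: −0.67). Leaving out any of control 1, control 2 or shKDM6B 1 ended both calls (adjusted p 0.0798 to 0.178), as did shKDM6B 3 for YWHAZ (0.0545), and control 3 or shKDM6B 2 for SDHA (0.0886 and 0.0675). With slide as a block both calls were lost too (0.0509 and 0.0975), and the mean of the YWHAZ probes was 0.14 (adjusted p = 0.398, the highest of 22 alternatives, from 0.00135). Of 14 replication histone genes, whose normal transcripts lack a poly(A) tail, 2 rose and 12 did not pass, also adjusted over the list alone (camera adjusted p = 0.980). H2AC6 rose by 0.65 ± 0.13, a call lost with the mean of its 2 probes (0.36, adjusted p = 0.108, the highest of 22 alternatives, from 0.00171). The median change of all 15312 genes was 0.08, and other scalings moved it by less than 0.1.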

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

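Of the tests in this part, those of scan date for the NF-kB and G2/M lists and those of leukocyte RNA and of an interferon response were chosen after the results were seen, and the correction for probe GC content was an alternative added after seeing the data.

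Probes without a gene name were left out of the comparisons by gene, and they changed in both directions. Of 5992 such kept probes measured on all 6 arrays, 1047 passed the threshold, against 4190 of 15312 in the fit by gene. In shKDM6B, 604 were higher than in control and 443 lower, with 360 changed at least 2-fold. The largest rises were probe A_23_P247 on chromosome 1, bases 151295427 to 151295486, at 6.76 ± 0.17 (SE; adjusted p = 1.61e-05), and probe A_32_P192842 on chromosome 8, bases 23755810 to 23755869, at 6.01 ± 0.28 (adjusted p = 0.000154). Probe A_23_P247 lies within the chromosome 1q21 region described further below. Which transcripts these probes measure was not analysed here.

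The brightest CEBPA probe misses the threshold while the other CEBPA probes pass it. A candidate explanation is a scan batch that shifts GC-rich probes. The 14 kept probes of the same GC content had a median shift of 0.66 between scans (second minus first, central 95% −0.07 to 1.99). The median shift was 0.08 for all kept probes, and the brightest CEBPA probe shifted by 1.43. With 14 probes the central 95% spans nearly all their values, so a shift inside it is weak evidence. With scan as a block the adjusted p of the brightest probe was 0.0180, so the miss may rest in part on that batch. Over the alternatives that represent the gene by this probe, the adjusted p ran from 0.00478 (replicate number as a block) to 0.438. Scan does not account for all of the spread: shKDM6B 1 and shKDM6B 3, both of the second scan, measured 3.13 and 4.51. Cross-hybridisation of a GC-rich probe was not tested. That the knockdown lowers CEBPA stays an open biological explanation of the lower values, untested beyond these 6 arrays.

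The rise of the NF-kB and inflammatory list is too large for scan date alone, since the smaller of the medians within the 2 scans was 1.24. Leukocyte RNA would bring all abundant leukocyte transcripts, but only 1 leukocyte marker (CSF1R, also in the list linked to C/EBPα) rose, 3 fell and 8 did not pass. The CSF1R call was lost without control 1, control 2, shKDM6B 1 or shKDM6B 3 (adjusted p 0.115 to 0.150). BxPC3 cells themselves gave signal for 12 of the 16 markers. The most abundant markers were LCP1 (4.66 in control, 4.73 in shKDM6B) and LAPTM5 (2.39 and 1.77). An interferon response to the vector would raise the interferon-stimulated genes together, but 5 rose and 8 fell. The knockdown, or an effect of the hairpin other than on KDM6B, may underlie the rise as an untested hypothesis, and the number of hairpins is not given in the sources used here.

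The fall of the G2/M list kept a median of −0.44 after each array's trend on probe GC content was removed, and the median nearer to 0 of the medians within the 2 scans was −0.36. Neither the GC trend nor scan date is therefore the whole cause. A difference in cell density or growth at harvest is not given in the sources used here and was not tested, and slower growth after the knockdown may be involved, as an untested hypothesis.

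The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. For genes changed, 1 of the 10 splits (the real one) gave as many: 4190, with 178 as the highest of the others, from the split that follows scan date. For lists, 8 of the 10 splits, the real one included, gave as many as the real value of 3, and the highest other gave 10. Each other split divides the groups unevenly, so it keeps part of the group difference. The list counts of these splits are therefore no clean measure of chance. The split that follows scan date gave 6 lists. With scan as a block the NF-kB, G2/M and cholesterol lists had adjusted p of 5.7e-12, 0.000200 and 0.000920. With an estimated correlation in place of the preset 0.01 the adjusted p were 0.227, 0.260 and 0.565.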

How the results depend on the processing

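Removing each array's GC trend and leaving out both arrays numbered 3 were chosen after seeing the data. The cause was not tested where a result changed, unless stated.

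Against 4190 genes changed (2376 higher, 1814 lower, 1154 at least 2-fold), array quality weights gave 8720 (5087 higher, 3633 lower). Each kept probe on its own gave 6339 probes (2936 lower, 1982 at least 2-fold), where probes and not genes were counted. Changes of at least 2-fold numbered 666 after normexp and 706 in the authors' log2 values. Leaving out 1 array gave 1971 (without control 1) to 4547 (without shKDM6B 2) genes, 1134 to 2758 higher and 837 to 1789 lower; 2209 passed without control 2 and 2283 without shKDM6B 1. With the replicate number as a block 5828 passed. The values cannot settle whether the numbers pair the samples, since number and scan overlap. Deviations of arrays of the same number correlated at −0.19 for number 1, whose arrays were in different scans. They correlated at 0.57 and 0.56 for numbers 2 and 3, each from 1 scan. Arrays of different number in the same scan gave 0.41 and 0.24.

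Against 3 lists shifted, the mean of a gene's probes gave 7, each probe on its own 9, fry 16, camera with an estimated correlation 0 (3 at an unadjusted p under 0.05), and leaving out 1 array 3 to 6 (6 without shKDM6B 1). By fry the duct and p53 lists turned from down to up (adjusted p = 0.0120 and 0.0318). The fit is the same, so their medians stayed at −0.052 and −0.049, and their means are positive (0.34 and 0.10). Camera compares a list with other genes and fry does not, so the 2 directions answer different questions.

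KDM6B was −0.37 after normexp (adjusted p = 0.109, range 4.4e-05 to 0.109); it could not be tested in the authors' log2 values or with probes required above background on all 6 arrays. CEBPA, not past the threshold, passed with the mean of its probes (−1.19), the replicate block (−1.17), the scan block (−1.64), the slide block (−1.58), the GC trend removed (−1.06), and probes A_23_P375494 (−1.21) and A_24_P224727 (−1.20), and ranged from −1.81 (without shKDM6B 3, passed) to −0.58 when 1 array was left out.

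Of 143 named genes past the threshold, KDM6B lost it after normexp, and 38 besides KDM6B lost it under at least 1 alternative. The mean of the ATF3 probes was −0.014, against 0.47 for its brightest probe. Over the alternatives and the named genes other than KDM6B and CEBPA, 2951 values kept their side of the threshold. Of the rest, 195 lost it, 11 gained it and 1 reversed. For lists, 806 kept their side, 3 lost it, 29 gained it and 2 reversed. Of the directions of lists not called, 55 of 768 differed. Signal over background limits folds of dim probes, and 68.3% to 78.7% of probes were well above background per array.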

Other observations

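The test of chromosome 1q21 in this part was chosen after the result was seen, and so was the choice of PEG10.

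Several of the largest rises lie in the epidermal differentiation complex on chromosome 1q21, bases 150222044 to 151884338, which holds genes of the cornified envelope and S100 proteins. Of 44 genes tested there, 14 rose, 3 fell and 27 did not pass. Beyond the genes named by rule, SPRR2E rose by 2.77, SPRR2G by 2.47, LCE2D by 2.40 and S100A12 by 2.16, while FLG, which encodes filaggrin, fell by 2.10; these were named after their values were seen. A regional rise may be one hypothesis. The region's median change of 0.31 lay at percentile 98.2 of 10000 random lists of the same size and signal (central 95% −0.04 to 0.30). Without the 8 genes named by rule, the other 36 (7 rose, 2 fell) had a median of 0.18 at percentile 61.3, inside the central 95% of −0.04 to 0.33, so the high percentile comes with the genes that prompted the test. The region was picked for its large rises and the 8 genes for the size or significance of their changes, so neither percentile decides on a regional rise, which stays open. The 3 falls, FLG among them, show that not each gene of the region rose. Near-identical SPRR2 members can share probe signal.

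H19 and PEG10, both imprinted, fell: H19 by 4.48 ± 0.23 and PEG10, which encodes a retrotransposon-derived protein, 5.66-fold (adjusted p = 0.000275). A shared fall of imprinted genes may be one hypothesis, but the other 27 imprinted genes tested had a median change of 0.01 at percentile 39.0 of 10000 random lists (central 95% −0.18 to 0.28). Of these, 3 rose (TFPI2, GRB10 and PHLDA2), 1 fell (CDKN1C) and 23 did not pass. The other imprinted genes therefore showed no fall as a whole. Their median cannot exclude a fall shared by a smaller group of imprinted genes, and CDKN1C fell too.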
